A study of Homo sapiens with 4 samples.

How the data were processed

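RNA labelled as from SKBr3 cells was hybridised to 4 Agilent 2-colour arrays, 2 labelled miR101 overexpression against a miR101 control and 2 labelled EZH2 RNAi against an EZH2 control siRNA. Per the labels, the treated RNA carried Cy5 and the control RNA Cy3 on all 4 arrays. There was no dye swap, so a gene's dye effect is part of its mean ratio, and a dye effect common to all arrays cancels only in the difference between treatments. The labels number the replicates 1 and 2 and do not say whether they came from separate cultures, so the p-values measure only the spread between arrays, which may be technical.

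The authors deposited a scanner table for each array, made with Agilent Feature Extraction 9.5.1.1 per the file headers. Each holds 45015 spots, 43376 of them non-control, with 41000 distinct probes, 264 of them printed at 10 spots. The deposited mean and background signals are intensity values on a linear scale. The deposited LogRatio column is a log10 ratio of red over green from the scanner software's own background subtraction and dye normalization, and the deposited PValueLogRatio column is a p-value of that log ratio from its error model, per the file headers. The authors' series table held values equal to the deposited log10 ratios within 1e-09 on every array, so its scale is log10, its direction red over green, and its column medians are 0. It held 0 columns from outside the series. The processed files name the hg18 build for probe positions.

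From the deposited intensity values, mean signals were background corrected with normexp and an offset of 50 on the median backgrounds, and log2 ratios were normalized by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Files were read with the data.table package, version 1.17.8, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Outlier spots were left out (123, 173, 94 and 108 on miR101 replicates 1 and 2 and EZH2 RNAi replicates 1 and 2), and spots of 1 probe were averaged. A gene was represented by its probe of highest mean intensity over the 4 arrays. It was tested where that probe was well above background in at least 1 channel on both arrays of at least 1 group, which left 19425 of 30499 names. Among 5328 genes with several probes, 367 on the arrays labelled miR101 and 679 with EZH2 RNAi had probes called in both directions. Names were updated through a reference gene table of assembly GRCh38.p14, used for names only: 15884 matched by accession, 1252 by symbol and 667 by synonym, and 12696 were kept as in the file.

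Median background was between 41.5 and 48 in Cy3 and between 50.5 and 53.5 in Cy5, against median signals from 101.9 to 139.2 and from 125.6 to 162.1. The SD of the ratios over genes was 0.702 and 0.651 on the arrays labelled miR101 and 0.484 and 0.474 with EZH2 RNAi. The number of arrays limits the precision, and the median standard error of a group mean was 0.0683 in log2 units.

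All 4 arrays entered 1 fit in limma (lmFit and eBayes) with a mean per group, 2 residual degrees of freedom and 24.53 prior degrees of freedom. Each group mean was tested against 0 and the 2 means against each other, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. A gene with 1 channel not well above background on both arrays of a group was given as a bound. The bound is the bright channel's mean against the higher of the dim probe's own signal and the lowest signal among probes well above background, from channel values after loess and Aquantile normalization, and is open to dye bias. There were 945 such genes on the arrays labelled miR101, 710 of them called, and 635 with EZH2 RNAi, 339 of them called.

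For 28 fixed gene lists, camera in limma with a preset correlation of 0.01 tested whether a list moved apart from other genes. Camera under an estimated correlation and fry were alternatives, with adjustment over the 28 lists per comparison. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the fit. Few calls can pass then, so a call lost under it does not show that correlation between genes caused the loss. The rule for named genes took PRC2 genes, the 10 highest and 10 lowest per comparison with both channels above background, up to 5 bounds, the 8 highest and 8 lowest of the difference, the 6 most shared in each direction, and up to 4 members per list. The groups, the fit, the lists, the naming rule and most alternatives were chosen before the data were examined. Arrays of the same replicate number came from the same scan per the file headers (scan 1 and scan 2), so the replicate block and the scan block are 1 fit. Deviations from the group means of same-numbered arrays correlated at 0.0115 across genes.

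The analysis was tested on simulated data for the miR101 comparison over 19425 genes. It recovered 100 of 100 genes changed by 1.5-fold and 100 of 100 changed by 2-fold, with 19 false calls. It made 0 calls in the comparison without changes, and called a list shifted by 0.5. The simulated genes were independent, with a spread drawn from the fit, and 100 were changed at each fold. In the data, 76.9% of genes were called in the miR101 comparison. The simulation therefore does not test dye effects, normalization, correlation between genes or a control RNA that stands apart. Alternatives covered the background correction, the scanner software's signals, the series table, median centring, scaling between arrays, filters on dim probes, the rule for several probes, separate fits, an intensity trend, the replicate block, leaving out each array, fold minimums, the scanner software's p-values, another control channel, the turned sign and centring on spike-ins. The other control channel set Cy5 of a miR101 array against Cy3 of an EZH2 RNAi array, after loess and Aquantile normalization. The 2 groups then shared control channels, and the fit ignored this sharing in its p-values and counts. A test of miR-101 seed sites was not run, since no 3' UTR sequences were used here.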

Results

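Gene expression was measured on 4 Agilent 2-colour arrays with RNA labelled as from SKBr3, a human breast cancer cell line that carries an amplified ERBB2 gene. On 2 arrays, RNA from cells labelled as overexpressing miR101, a microRNA described as lowering EZH2, was set against RNA from miR101 control cells. On the other 2 arrays, RNA from cells with RNA interference (RNAi) against EZH2 was set against RNA from cells with a control siRNA. EZH2 is the histone methyltransferase of Polycomb repressive complex 2 (PRC2), which keeps developmental genes silent. The treated RNA carried Cy5 and the control RNA Cy3 on every array, so each value is a log2 ratio of treated over control. Between 56.05% and 65.27% of the non-control spots were well above background in Cy3, and between 63.89% and 71.2% in Cy5. No spot was saturated (0 on each array), and 19425 genes were tested. The number of arrays, 2 per group, limits the precision. The series sets the 2 treatments side by side, which asks how far the expression change with added miR101 resembles that with loss of EZH2.

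EZH2 itself was 2.6-fold lower in the EZH2 RNAi cells than in the control siRNA cells, with log2 ratios of -1.51 and -1.24 on the 2 arrays (mean -1.38 ± 0.19, SD, n = 2). On the arrays labelled miR101 overexpression, EZH2 was 1.27-fold higher in the treated channel (mean 0.35 ± 0.065, SD, n = 2), which is opposite to the lowering described for miR-101. The arrays are therefore named by their labels throughout. EED and SUZ12, the core subunits that EZH2 needs for its activity, followed the same pattern. EED fell with EZH2 RNAi (-0.86 ± 0.036) and was higher on the arrays labelled miR101 (0.72 ± 0.031), and SUZ12 fell with EZH2 RNAi (-0.69 ± 0.18) and was higher on the arrays labelled miR101 (1.36 ± 0.059). EZH1, the alternative methyltransferase of the complex, rose with EZH2 RNAi (0.55 ± 0.13) and was lower on the arrays labelled miR101 (-0.22 ± 0.079).

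Among the accessory PRC2 genes, JARID2 rose with EZH2 RNAi (1.23 ± 0.13) and was 0.07 ± 0.18 on the arrays labelled miR101, where it did not pass the test. MTF2 rose in both comparisons (0.78 with EZH2 RNAi and 1.65 on the arrays labelled miR101). AEBP2 rose on the arrays labelled miR101 (0.59) and was 0.01 with EZH2 RNAi, and that difference passed the test (0.57, adjusted p = 2.23e-05 in limma with Benjamini-Hochberg adjustment). RBBP7 (-0.48), PHF19 (-0.26) and RBBP4 (-0.20) were lower with EZH2 RNAi but lay above 0 with median centring in place of loess (0.22, 0.34 and 0.30). On the arrays labelled miR101, PHF19 (-0.32) and PHF1 (-0.22) were lower, while RBBP4 (0.14) and RBBP7 (-0.11) did not pass, nor did PHF1 with EZH2 RNAi (0.14). Of the 11 PRC2 genes, 3 were higher, 6 lower and 2 not past the test with EZH2 RNAi, and 5 were higher, 3 lower and 3 not past it on the arrays labelled miR101, with the same counts adjusted over the list alone. As a group they did not move apart from other genes (limma's camera, Benjamini-Hochberg adjusted p = 0.69 with EZH2 RNAi and 0.46 on the arrays labelled miR101).

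**Figure D1:**
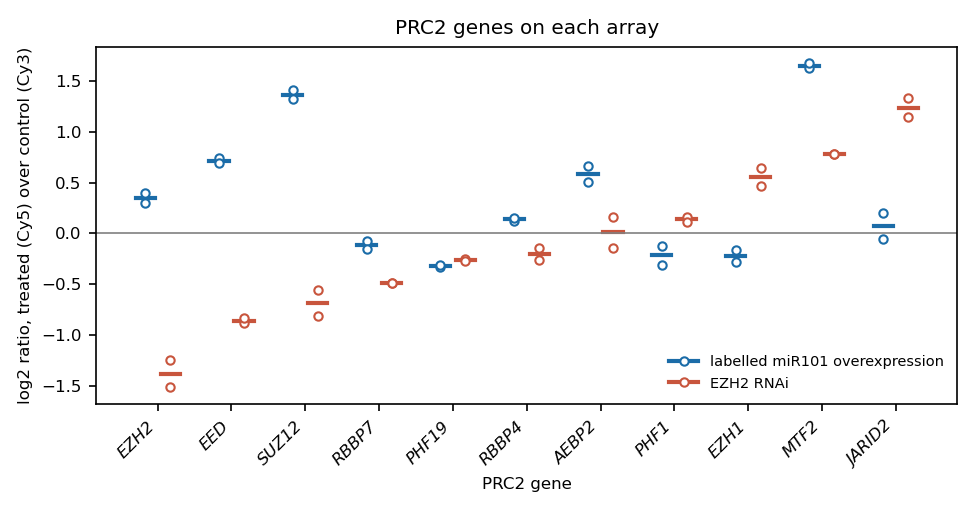
Log2 ratios of treated over control for the 11 PRC2 genes on each of the 4 arrays, with open circles for single arrays and bars for the mean of the 2 arrays of a group. EZH2 lies at -1.51 and -1.24 with EZH2 RNAi and at 0.30 and 0.39 on the arrays labelled miR101 overexpression, and the EZH2 RNAi values of RBBP7, PHF19 and RBBP4 turn positive with median centring.

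In limma with Benjamini-Hochberg adjustment, the EZH2 ratio had an adjusted p = 3.34e-15 with EZH2 RNAi and 9.12e-05 on the arrays labelled miR101. The EZH2 probe lies on chromosome 7 from 148135454 to 148135513 on the minus strand (hg18, per the file headers). No gene annotation of that build was used here, so its exon is not stated. A dimmer EZH2 probe at 148202052 to 148202111, above background in 7 of 8 channels, gave means of 0.29 on the arrays labelled miR101 and -0.19 with EZH2 RNAi. The other 2 SUZ12 probes gave -0.30 and -0.25 with EZH2 RNAi, and they disagreed on the arrays labelled miR101 (-0.22 and 0.68). The control channel of the miR101 arrays stood apart: its log2 EZH2 signal was 12.60 and 12.78, against 13.88 and 13.58 in the control channel of the EZH2 RNAi arrays and 12.91 and 13.18 in the channel labelled miR101 overexpression. With the EZH2 control siRNA channel of the same slide as the control, EZH2 on the miR101 arrays was -0.69 (adjusted p = 0.0021 in limma). This choice was made after seeing the data, and it was the only one of 17 alternatives in which the direction of EZH2 turned. Turning the sign of the miR101 ratios, which reverses that direction by construction, was not among the 17.

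With EZH2 RNAi, secreted matrix proteases rose furthest. MMP3, a stromelysin, was 40.6-fold higher (log2 5.34 ± 0.008, SD, n = 2), and MMP1, an interstitial collagenase, was 29.7-fold higher (4.89 ± 0.11). The metalloprotease ADAMTS6 (2.76 ± 0.033) was also among the 10 highest. INHBA, a subunit of activin (2.56 ± 0.075), and GDF15, a stress-induced growth factor (2.50 ± 0.084), rose as well. The kinetochore gene CENPF fell furthest, 6.32-fold lower (-2.66 ± 0.10), and the 10 lowest also held the spindle gene ASPM (-2.07 ± 0.16), the survivin gene BIRC5 (-1.91 ± 0.098) and CIT, a kinase of cytokinesis (-1.86 ± 0.19).

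Also among the 10 highest were MYO16 (2.56), STK38L (2.40), RAB8B (2.35) and C21orf91 (2.34). The other genes among the 10 lowest were PIR, the pirin gene (-2.42), GNAZ, a G protein subunit (-2.19), TEX19 (-2.16), DUSP13A (-2.03), PPP1CB, a catalytic subunit of protein phosphatase (-1.89), and H1-2, a linker histone (-1.85). The genes named from these 2 groups had adjusted p of at most 1.8e-20 when higher and 1.1e-17 when lower (limma, Benjamini-Hochberg). IL1RL1, an interleukin receptor, was not well above background in the control siRNA channel and was at least 11.3-fold higher with EZH2 RNAi. By the same bound DHRS9 was at least 3.41-fold, AADAC at least 3.33-fold, DCLK1 at least 2.41-fold and GNAL at least 2.39-fold higher. In all, 6219 of 19425 genes were higher and 6516 lower at an adjusted p under 0.05 in limma, of which 1577 and 2014 moved by at least 1.5-fold. Median centring in place of loess, on all non-control spots, moved the median of the tested genes to 0.22 and gave 9851 higher and 2685 lower.

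The fixed lists of cell cycle genes fell together with EZH2 RNAi. All 35 genes of the G2/M and mitosis list were lower, 32 of them by at least 1.5-fold, with a mean of -1.01, and the examples beside CENPF and BIRC5 were HMMR (-1.84) and CENPE (-1.42), which act on the mitotic spindle. Adjusted over the list alone, 35 were lower. The list moved apart from other genes (camera in limma, Benjamini-Hochberg adjusted p = 5.4e-17), which was lost at adjusted p = 0.30 with an estimated correlation. Of 36 genes of G1/S and DNA replication, 33 were lower, 1 higher and 2 not past the test (34 lower and 1 higher adjusted over the list alone), with a mean of -0.70. They included CDC45, a part of the replicative helicase (-1.73), the transcription factor E2F2 (-1.27) and the DNA ligase LIG1 (-1.25). Camera in limma gave an adjusted p = 2.5e-11 for this list, and adjusted p = 0.30 with an estimated correlation. Both list calls stayed past the threshold in 15 of 16 alternatives. Member counts of these and the other lists rest on loess and were not recounted with median centring. Under median centring, 67.5% of all calls with EZH2 RNAi kept their direction and 746 turned.

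Among the lists higher with EZH2 RNAi were 3 of induced genes. Of 25 immediate early genes, 17 were higher, 5 lower and 3 not past the test, the same counts adjusted over the list alone, with a mean of 0.56. The transcription factors EGR2 (2.11), EGR1 (2.06) and ATF3 (1.77) and the phosphatase gene DUSP5 (1.36) led them (camera adjusted p = 3e-04 in limma, adjusted p = 0.55 with an estimated correlation). Of 19 inflammatory NF-kB genes, 14 were higher, 4 lower and 1 not past the test, again the same adjusted over the list alone. RELB, an NF-kB subunit (1.58), SOD2, a mitochondrial superoxide dismutase (1.44), NFKBIA, an inhibitor of NF-kB (1.00), and the cytokine gene IL1B (0.95) led them (camera adjusted p = 0.0013 in limma, adjusted p = 0.66 with an estimated correlation). Of 29 genes of the unfolded protein and ATF4 response, 19 were higher, 8 lower and 2 not past the test, as they were adjusted over the list alone. They included DDIT3, the CHOP transcription factor (1.505), CHAC1, which degrades glutathione (1.08), and the chaperone gene DNAJB9 (0.98), with a camera adjusted p = 0.0083 in limma and adjusted p = 0.58 with an estimated correlation.

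Of 36 interferon response genes, 22 were lower, 8 higher and 6 not past the test with EZH2 RNAi (22 lower and 9 higher adjusted over the list alone), with a mean of -0.26 that turned to 0.20 with median centring. SAMD9 (-1.58) and IFI44L (-1.13) fell, while the antiviral gene RSAD2 (1.52) and the peptide transporter gene TAP1 (1.15) rose. Camera in limma gave the list an adjusted p = 0.032, and adjusted p = 0.58 with an estimated correlation. It stayed past the threshold in 11 of 16 alternatives. Genes that Polycomb complexes are known to silence did not pass as groups in camera among the members tested. Those were 11 of 39 HOX genes, 23 of 52 developmental transcription factors and 21 of 30 genes described as repressed by EZH2 in cancer. Members without a detected probe were not tested, so genes silent in all channels were left out. Of 11 HOX genes, 5 were higher, 2 lower and 4 not past the test, led by HOXD1 (1.48), with a camera adjusted p = 0.54 in limma. Of 23 developmental transcription factors, 11 were higher, 4 lower and 8 not past the test, led by GATA6 (1.29), with an adjusted p = 0.21. Of 21 genes described as repressed by EZH2 in cancer, 8 were higher, 6 lower and 7 not past the test, and the metalloprotease inhibitor genes TIMP2 (1.08) and TIMP3 (-1.001) went opposite ways (camera adjusted p = 0.67 in limma). These 3 lists had the same counts adjusted over the list alone. Limma's fry, which does not compare a list with other genes, called HOX genes (adjusted p = 0.049) and developmental transcription factors (0.033) higher. It gave the genes described as repressed by EZH2 an adjusted p = 0.05.

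On the arrays labelled miR101 overexpression, the highest ratios belonged to genes of several functions. CLIC4, a chloride intracellular channel protein, was 8.45-fold higher in the treated channel (log2 3.08 ± 0.080, SD, n = 2), ANKRD1, a stress-responsive ankyrin repeat gene, 7.71-fold (2.95 ± 0.005), and the polarity gene PARD6B 7.56-fold (2.92 ± 0.13). TGFB2, a transforming growth factor (2.79 ± 0.062), RECK, an inhibitor of matrix metalloproteases (2.76 ± 0.14), and RDX, which links actin to the membrane (2.84 ± 0.13), were also among the 10 highest. The lowest included the nuclear lamina gene LMNB1 (-1.92 ± 0.031), FOXM1, a transcription factor of mitotic genes (-1.71 ± 0.069), the chromatin reader BRD3 (-2.06 ± 0.25) and the AP-1 subunit FOSL1 (-1.69 ± 0.067).

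The other genes among the 10 highest were CYP1B1, a cytochrome P450 (2.88), EML4, which binds microtubules (2.87), NCOA7 (2.84) and ITPR1, a calcium release channel (2.74). The other genes among the 10 lowest were SPRYD4 (-2.27), PDAP1 (-2.19), the cytokine gene IL11 (-1.80), the kinase gene CSK (-1.71), the histone variant gene H2AZ2 (-1.69) and ND3, a mitochondrial subunit of respiratory complex I (-1.65). These 20 genes had adjusted p of at most 3.1e-21 when higher and 5.4e-18 when lower (limma, Benjamini-Hochberg). In the miR101 control channel, the coactivator gene PPARGC1A was not well above background, and it was at least 2.66-fold higher in the treated channel. By the same bound NPR3 was at least 2.45-fold, ANGPT1 at least 2.35-fold, GPR155 at least 2.2-fold and the receptor gene ERBB4 at least 2.14-fold higher. In all, 8155 genes were higher and 6789 lower at an adjusted p under 0.05 in limma, of which 4400 and 2056 moved by at least 1.5-fold and 2388 and 371 by at least 2-fold. The balance turned with the scanner software's signals (7378 higher and 8485 lower) and with the authors' series table (7379 and 8480). The control channel of these arrays stood apart, with 2960 genes at least 2-fold away from the other control channel, against 436 for the treated channel. With that other control channel, chosen after seeing the data, 6030 genes were higher and 3593 lower.

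Interferon response genes rose together on the arrays labelled miR101 overexpression. Of 36 genes, 30 were higher, 2 lower and 4 not past the test, 27 of them by at least 1.5-fold, with the same counts adjusted over the list alone and a mean of 1.07. GBP1, an interferon-induced GTPase, was highest (2.52 ± 0.090), with IFI44L (2.25 ± 0.078), IFIT2, which binds foreign RNA (2.12 ± 0.003), and IFIH1, a sensor of double-stranded RNA (2.11 ± 0.11). Camera in limma gave an adjusted p = 2.9e-07, and adjusted p = 0.71 with an estimated correlation. Against the EZH2 control siRNA channel, the list's median log2 difference was -1.16 in the miR101 control channel and -0.25 in the channel labelled miR101 overexpression. With the EZH2 control siRNA channel as the control, the list's mean was -0.19 (camera adjusted p = 0.0039 in limma, adjusted p = 0.51 with an estimated correlation).

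Genes of G1/S and DNA replication fell as a list on these arrays, with 22 lower, 9 higher and 5 not past the test, the same adjusted over the list alone. UNG, a DNA glycosylase (-1.25), the helicase gene MCM7 (-1.14) and LIG1 (-1.11) fell, and the polymerase gene POLA1 rose (1.18). Camera in limma gave an adjusted p = 0.02, and adjusted p = 0.71 with an estimated correlation. The G1/S list stayed past the threshold in 13 of 17 alternatives. Ribosomal protein genes rose, with 34 of 47 higher, 2 lower and 11 not past the test, among them RPL5 (1.03), RPS27 (0.99), RPL6 (0.98) and RPS14 (0.80). Their list mean was 0.32 and 0.38 on the 2 arrays (camera adjusted p = 0.02 in limma, adjusted p = 0.71 with an estimated correlation). That call ended with the replicate number, which is also the scan, as a block (adjusted p = 0.29), and without replicate 1 (0.15) or replicate 2 (0.36) of the arrays labelled miR101, and the range over 17 alternatives was 9.7e-05 to 0.71. Of 16 BCL2 family genes, 11 were lower, 2 higher and 3 not past the test, with means of -0.26 and -0.30 on the 2 arrays. The death-promoting genes BOK (-1.13), BAX (-1.07) and BBC3 (-1.07) fell, and PMAIP1, which also promotes death, rose (2.12). This list had a camera adjusted p = 0.029 in limma and adjusted p = 0.71 with an estimated correlation. Its call ended with the block (adjusted p = 0.091) and without replicate 1 (0.077) or replicate 2 (0.11) of these arrays, over a range of 0.0071 to 0.71. With the EZH2 control siRNA channel as the control, the BCL2 family mean was -0.01 (adjusted p = 0.66 in limma), the ribosomal mean 0.22 (adjusted p = 0.06) and the G1/S mean -0.25 (adjusted p = 1.3e-04, 0.51 with an estimated correlation). The BCL2 family mean in the miR101 control channel was 0.27 against that channel (adjusted p = 0.29 in limma). The ribosomal and BCL2 lists had the same counts adjusted over the list alone. The G1/S list mean was -0.26 on each of the 2 arrays.

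The genes described as miR-101 targets did not pass as a group in camera on these arrays. Of 26 tested, 13 were lower, 9 higher and 4 not past the test, the same adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.37 in limma). ATG4D, an autophagy protease (-1.29), and the transcription factor SOX9 (-1.11) fell, while RAP1B, a small GTPase (1.62), and PRKAA1, a subunit of AMP-activated kinase (1.104), rose. Without EZH2 and EED, a split that was not planned, 13 of 24 were lower and 7 higher, with a median of -0.17. Both were higher on these arrays, so leaving them out can only lower the median. In the channel labelled miR101 overexpression the 26 genes had a median log2 difference of -0.23 from the EZH2 control siRNA channel, and in the miR101 control channel one of -0.21. G2/M and mitosis genes were higher for 25 of 35, lower for 8 and not past the test for 2, the same adjusted over the list alone, led by TOP2A, the topoisomerase that untangles DNA (2.14), ECT2 (1.71), CENPF (1.57) and NUSAP1 (1.30). The list missed the threshold (camera adjusted p = 0.062 in limma), and its median was -0.65 in the miR101 control channel and 0.03 in the treated channel, both against the EZH2 control siRNA channel. No list call in any comparison held with an estimated correlation, 0 of 28 lists each. That test rests on 2 residual degrees of freedom, so this does not show that correlation between genes undid the calls. For the G1/S list with EZH2 RNAi the estimated correlation was -0.02, under the preset 0.01. The unadjusted p of camera in limma still went from 1.8e-12 to 0.015. With fry, which tests whether a set's genes on balance move one way, 22 lists passed on the arrays labelled miR101, 15 with EZH2 RNAi and 17 in the difference. Fry called the described miR-101 targets lower on the arrays labelled miR101 (adjusted p = 0.0039 in limma), higher with EZH2 RNAi (0.0022) and lower in the difference (0.0019). In the difference, 14 of them were lower and 5 higher, and camera in limma gave an adjusted p = 0.086.

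**Figure D2:**
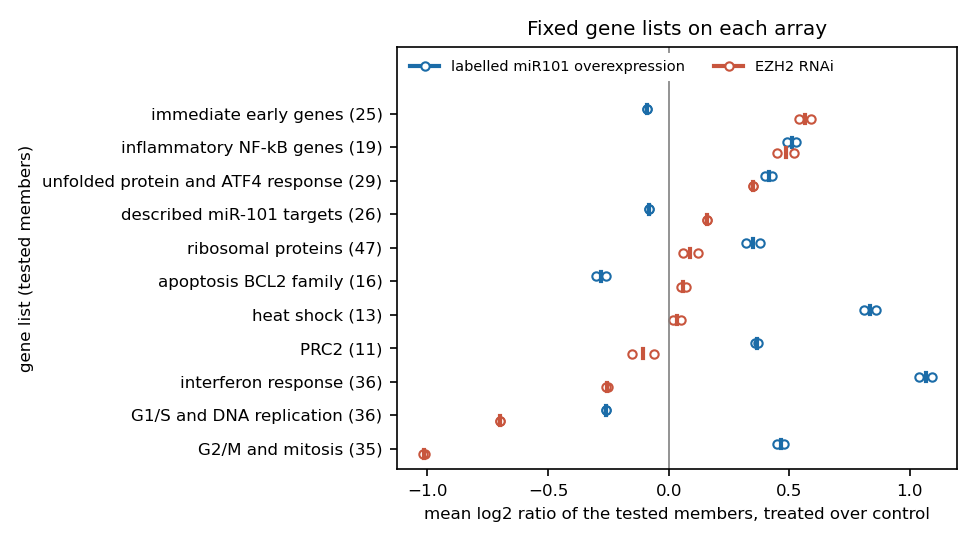
Mean log2 ratio of treated over control for the tested members of 11 fixed gene lists on each of the 4 arrays, with open circles for single arrays, ticks for the group mean and the number of tested members in brackets. The interferon response list lies at 1.09 and 1.04 on the arrays labelled miR101 overexpression and at -0.25 and -0.26 with EZH2 RNAi (0.20 as a mean with median centring), and the G2/M list at 0.48 and 0.45 against -1.01 and -1.02.

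Set against each other in the direction of the labels, the treatments had these largest differences. The difference, miR101 minus EZH2 RNAi, was 4.23 for CENPF, which was 1.57 on the arrays labelled miR101 and -2.66 with EZH2 RNAi, 4.15 for PIR, 4.05 for PPP1CB and 3.73 for ASPM. The actin-associated genes LIMCH1 (4.02) and PDLIM5 (3.83), the microtubule gene MAP9 (3.91) and ENPP1, which makes pyrophosphate (3.88), completed the 8 highest. At the low end stood MMP3 (-5.44), MMP1 (-4.33), FOSL1 (-2.56), PAQR5 (-2.50), ND3 (-2.42), the methyltransferase subunit WDR5 (-2.38), BRD3 (-2.37) and B3GALNT2 (-2.31). EZH2 (1.73), EED (1.57) and SUZ12 (2.05) were higher in the difference and EZH1 was lower (-0.77). These values rest on the labelled direction of the miR101 ratios. With that sign turned, a choice made after seeing the data, the difference was 1.09 for CENPF, 0.69 for PIR, 0.41 for ASPM, -0.26 for PPP1CB, -5.24 for MMP3, -5.45 for MMP1, 0.82 for FOSL1 and 1.75 for BRD3. It was -1.14 for LIMCH1, -1.11 for ENPP1, -0.55 for PDLIM5, -0.36 for MAP9, -1.79 for PAQR5, 0.88 for ND3, -0.50 for WDR5 and -1.35 for B3GALNT2, so 8 of the 16 genes turned. AEBP2 was then -0.60. For EZH2 it was then 1.03, for EED 0.14, which did not pass the test, for SUZ12 -0.68 and for EZH1 -0.33.

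By limma with Benjamini-Hochberg adjustment, 7719 genes were higher and 6246 lower in this difference, 4826 and 2787 of them by at least 1.5-fold, and the 16 named genes had adjusted p of at most 8.2e-16. The counts depended on the scaling, with 5447 higher and 7078 lower with median centring, 6989 and 7568 with the scanner software's signals, and 15882 and 705 with centring on spike-ins, which was chosen after seeing the data. G2/M and mitosis genes were higher for 32 of 35, lower for 1 and not past the test for 2, the same adjusted over the list alone, with a mean of 1.48, TOP2A among them at 3.37 (camera adjusted p = 9.6e-10 in limma, adjusted p = 0.55 with an estimated correlation). Interferon response genes were higher for 31 of 36, lower for 4 and not past the test for 1, the same adjusted over the list alone, with a mean of 1.32 and GBP1 at 3.57 (camera adjusted p = 2.3e-07 in limma, adjusted p = 0.55 with an estimated correlation). With the EZH2 control siRNA channel as control of both groups, a choice made after seeing the data, the interferon mean was 0.07 (camera adjusted p = 0.92 in limma) and 5565 genes were higher and 3328 lower. That fit ignored that the groups then shared control channels. Immediate early genes were lower for 17 of 25, higher for 6 and not past the test for 2 (7 higher and 17 lower adjusted over the list alone), with a mean of -0.65, DUSP5 at -1.99 and EGR1 at -1.98 (camera adjusted p = 7.1e-04 in limma, adjusted p = 0.61 with an estimated correlation). With the sign of the miR101 ratios turned, the list means were 0.54 for G2/M, -0.81 for interferon and -0.48 for immediate early genes (camera adjusted p = 5.6e-04, 4e-04 and 0.41 in limma, 0.64, 0.64 and 0.70 with an estimated correlation). TOP2A was then -0.91, GBP1 -1.46, DUSP5 -0.74 and EGR1 -2.13. Turned, 4 other lists were called as well, G1/S (1.1e-08), NF-kB (0.003), the unfolded protein and ATF4 response (0.01) and ribosomal proteins (0.032, all camera adjusted p in limma), and none held with an estimated correlation. Within scan 1, the list means were 0.48 against -1.01 for G2/M, 1.09 against -0.25 for interferon and -0.09 against 0.54 for immediate early genes. Within scan 2 they were 0.45 against -1.02, 1.04 against -0.26 and -0.09 against 0.59.

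In the direction of the labels, some genes moved the same way in both comparisons, and with the sign of the miR101 ratios turned they moved opposite ways. ADAM10, a sheddase of the cell surface, was 1.78 on the arrays labelled miR101 and 1.94 with EZH2 RNAi. STK38L (1.70 and 2.40), RAB8B (1.68 and 2.35), GDF15 (1.61 and 2.50) and the adhesion gene CEACAM1 (1.82 and 1.45) also rose in both. IL11 fell in both (-1.80 and -1.79), as did IRAK1, a kinase of interleukin receptor signalling (-1.38 and -1.26), the non-coding RNA genes TYMSOS (-1.45 and -1.26) and MIR1915HG (-1.17 and -1.40), the polarity gene DLG5 (-1.40 and -1.20) and the glycosyltransferase gene MGAT5B (-1.18 and -1.27). These genes had adjusted p of at most 1e-14 on the arrays labelled miR101 and 6.2e-14 with EZH2 RNAi (limma, Benjamini-Hochberg).

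Over all genes, 2862 were higher in both comparisons and 2483 lower in both, where independent lists would give 2611 and 2277. Another 2967 were higher on the arrays labelled miR101 and lower with EZH2 RNAi (2736 for independent lists), and 1993 were the reverse (2174). At 1.5-fold or more, 525 genes were higher in both (357 for independent lists) and 349 lower in both (213), against 683 (456) and 91 (167) in opposite directions. By label, 5345 genes moved the same way and 4960 opposite ways, and turning the sign exchanges these 2 counts. Across genes, which are not independent replicates, the mean ratios of the 2 comparisons correlated with a Pearson r of 0.0226 and a Spearman rho of 0.0351. Arrays of the same scan correlated at -0.0158 and 0.0645 between treatments, while the 2 arrays of a treatment correlated at 0.983 for miR101 and 0.949 for EZH2 RNAi.

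**Figure D3:**
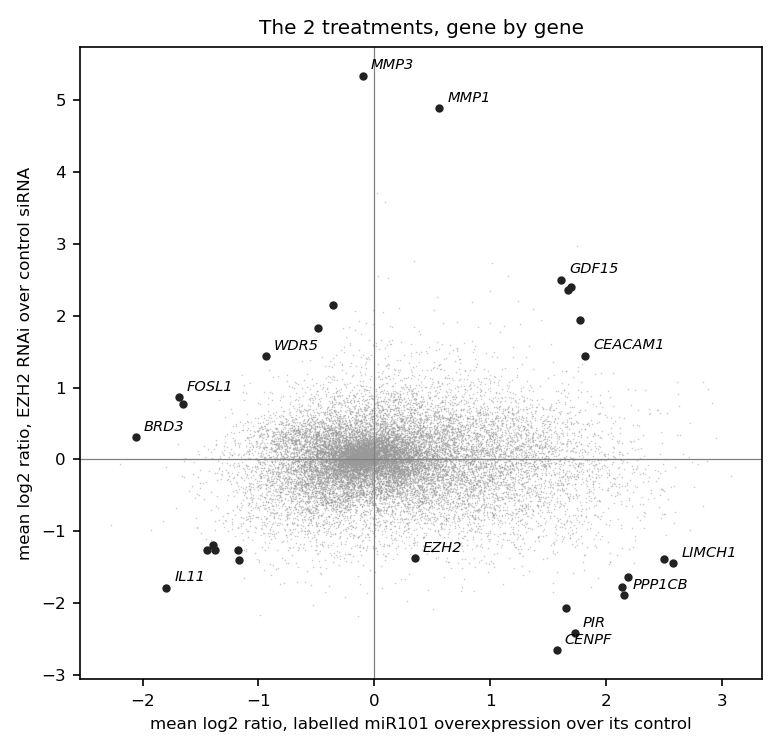
Mean log2 ratio with EZH2 RNAi (vertical) against that on the arrays labelled miR101 overexpression (horizontal), each grey point 1 of 19425 genes and each black point EZH2 or a gene named for the difference or the shared response, some with its symbol. MMP3 lies at 5.34 and -0.10, CENPF at -2.66 and 1.57, and the cloud has a Pearson r of 0.0226.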

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

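All tests of explanations in this part were chosen after the results they bear on were seen. The treatments differed by the test of the difference itself for 7719 genes higher and 6246 genes lower in miR101 minus EZH2 RNAi (limma, Benjamini-Hochberg). By camera in limma at a preset correlation, lists differed too, with means of 1.48 for G2/M and mitosis, 1.32 for the interferon response and -0.65 for immediate early genes, calls lost with an estimated correlation (adjusted p = 0.55, 0.55 and 0.61). With the EZH2 control siRNA channel as control of both groups, the interferon mean was 0.07 (adjusted p = 0.92 in limma, which ignores the sharing). The log2 difference was 4.23 for CENPF, 4.15 for PIR, 4.05 for PPP1CB, 4.02 for LIMCH1, 3.91 for MAP9, 3.88 for ENPP1, 3.83 for PDLIM5 and 3.73 for ASPM. It was -5.44 for MMP3, -4.33 for MMP1, -2.56 for FOSL1, -2.50 for PAQR5, -2.42 for ND3, -2.38 for WDR5, -2.37 for BRD3 and -2.31 for B3GALNT2. Among PRC2 genes it was 1.73 for EZH2, 1.57 for EED, 2.05 for SUZ12 and -0.77 for EZH1. These values rest on the labelled direction of the miR101 ratios. With that sign turned, the list means were 0.54 for G2/M, -0.81 for interferon and -0.48 for immediate early genes, the last not called and none called with an estimated correlation. The genes were then 1.09 for CENPF, 0.69 for PIR, -0.26 for PPP1CB, -1.14 for LIMCH1, -0.36 for MAP9, -1.11 for ENPP1, -0.55 for PDLIM5 and 0.41 for ASPM, and -5.24 for MMP3, -5.45 for MMP1, 0.82 for FOSL1, -1.79 for PAQR5, 0.88 for ND3, -0.50 for WDR5, 1.75 for BRD3 and -1.35 for B3GALNT2. EZH2 was 1.03, EED 0.14, not past the test, SUZ12 -0.68 and EZH1 -0.33.

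The arrays labelled miR101 overexpression had wide ratios, with 2759 genes called at 2-fold or more against 901 with EZH2 RNAi. A dye effect common to all arrays is argued against by the Pearson r of 0.0226 between the mean ratios of the 2 groups. This holds only if opposite responses in the 2 groups did not offset such an effect. A gradient along transcripts common to all genes cannot be told apart from a difference between the RNAs, since a gene's upstream probe differed from its downstream probe by a median of -0.17 on these arrays and 0.15 with EZH2 RNAi, and the distances of the probes from the transcript ends were not known. A control RNA that stands apart remains a candidate explanation, since 2960 genes were 2-fold apart between the 2 control channels, against 436 between the channel labelled miR101 overexpression and the EZH2 control siRNA channel. What set that control apart, including a biological difference between the control cultures or an effect of miR-101 on the treated cells, was not tested.

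EZH2 was higher, not lower, in the channel labelled miR101 overexpression. A control RNA low in EZH2 could account for this, since EZH2 in the miR101 control channel differed from the EZH2 control siRNA channel by -1.04, more than the ratio of 0.35, and the channel labelled miR101 overexpression differed from it by -0.69. An exchange of the channels after spike-ins were added would turn the spike-in ratios of these arrays. The lowest and highest spike-in were -3.436 and 2.692 on miR101 replicate 1. The same spike-ins were -2.74 and 3.271 on EZH2 RNAi replicate 1. Spike-ins nearer 0 could change sign, as E1A_r60_1 did (-0.609 and 0.509). These values argue against such an exchange if both groups received the spike-ins in the same orientation. An exchange of the RNAs before that step cannot be told apart from a control RNA low in EZH2. The EZH2 control siRNA channel correlated at 0.9884 with the channel labelled miR101 overexpression and at 0.9617 with the miR101 control channel, but a control that merely stood apart would give the same order. The described miR-101 targets do not settle it, since against the EZH2 control siRNA channel they had a median of -0.23 and a mean of -0.31 in the channel labelled miR101 overexpression (camera adjusted p = 0.0013 in limma, 0.51 with an estimated correlation) and a median of -0.21 and a mean of -0.23 in the miR101 control channel (adjusted p = 0.29 and 0.73).

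Interferon response genes were higher in the channel labelled miR101 overexpression. A dye effect common to all arrays, as the whole cause, is argued against by their median of -0.34 with EZH2 RNAi in the same dye orientation, and although median centring turned their mean there to 0.20, it was then 1.15 on the arrays labelled miR101, and the difference, in which such an effect cancels, was 0.95. A control RNA low in interferon genes remains a candidate explanation, since their median in the miR101 control channel was -1.16 against the EZH2 control siRNA channel. A response of the cells to added miR-101 cannot be told apart from it. Their median in the treated channel was -0.25 against the EZH2 control siRNA channel, which argues against a response only if the control siRNA did not itself raise these genes, and no untransfected cells were compared here.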

How the results depend on the processing

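The 2-fold minimum, the other control channel, the turned sign and spike-in centring were chosen after seeing the data. Fold minimums lower counts by construction. At 1.5-fold the higher and lower counts were 4400 and 2056 (miR101), 1577 and 2014 (EZH2 RNAi) and 4826 and 2787 (difference), and at 2-fold 2388 and 371, 385 and 516, and 2898 and 977. Genes moving the same way numbered 874 and 90, and opposite ways 774 and 134. The scanner software's p under 0.01 with 2-fold gave 3437 and 2104 (miR101), 780 and 997 (EZH2 RNAi), 343 the same way and 331 opposite. Median centring gave 9851 higher and 2685 lower with EZH2 RNAi, 78.6% higher against 48.8% with loess, and 43.5% against 55.3% in the difference, and r was 0.0799. It moved the median of the tested genes to 0.22 with EZH2 RNAi, and turned RBBP7 to 0.22, RBBP4 to 0.30, PHF19 to 0.34 and the interferon list to 0.20. Calls kept in the same direction under it were 83.5% for miR101, 67.5% for EZH2 RNAi and 78.4% for the difference. Spike-in centring gave 15882 higher and 705 lower in the difference, which follows from its shift of all ratios, and the amounts of spike-ins added to each channel were not known. The EZH2 control siRNA channel as control gave 3593 lower for miR101 and 3328 lower in the difference, and turned EZH2 to -0.69 and the interferon list to -0.19 on the miR101 arrays. The scanner software's signals gave 7378 higher and 8485 lower for miR101 and 6989 and 7568 in the difference, and with the series table these were 7379 and 8480, and 6988 and 7569. Turning the sign of the miR101 ratios gave 6325 higher and 7791 lower in the difference. For centring, the scanner software's signals and the other control, the cause was not tested.

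For miR101, 1 list was called with the scanner software's signals, 1 with the series table, 1 with the mean of a gene's probes, 7 without a filter, 0 with an estimated correlation and 22 with fry, against 4 as reported. With EZH2 RNAi, 10 were called without a filter, 0 with an estimated correlation and 15 with fry, against 6. In the difference, 7 were called with median centring, 6 without a filter, 0 with an estimated correlation and 17 with fry, against 3. The cause was not tested, except that fry does not compare a list with other genes. Camera with an estimated correlation rests on 2 residual degrees of freedom. Leaving out 1 array in turn, where the lone array is assumed to vary like the other group, gave 6858 to 8323 higher and 5256 to 7021 lower for miR101, 5309 to 6049 and 5719 to 6365 for EZH2 RNAi, and 6886 to 7539 and 5198 to 5892 for the difference. Genes moving the same way then numbered 4425 to 5045, and opposite ways 4162 to 4687, r was -0.019 to 0.0645, EZH2 was 0.30 to 0.39 and -1.51 to -1.24, and lists called were 3 to 4, 6 to 8 and 3. The replicate block, also the scan block, gave 8138 and 6753, 6222 and 6506, and 7714 and 6212 higher and lower, kept 99.3%, 99.2% and 99.2% of the calls, and left 3, 7 and 3 lists called, with ribosomal proteins and the BCL2 family no longer called for miR101. Of 3466 values of named genes under alternatives, 3441 kept direction and side of the threshold, 13 lost the call, 9 gained it and 3 turned, and no named gene other than EZH2 was run under the other control channel. The filters, separate fits, trend and block reuse the same ratios, so direction could not turn under them. The series table gave nearly the same calls as the scanner software's signals. Many named genes were picked for large ratios, so this tally is a weak test of robustness. Of 212 values of called lists, 173 kept both, 37 lost the call and 2 turned. Both tallies leave out the turned sign and spike-in centring. With the sign turned, some named genes of the difference changed direction, as given above, and the interferon list mean in the difference was -0.81. Seed-site alternatives were not run. Signals near background limit the ratios of 945 and 635 genes with 1 dim channel on the arrays labelled miR101 and with EZH2 RNAi.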

Other observations

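The tests here of marker detection, of spike-ins, of probe position and of the miR101 arrays against the EZH2 control siRNA channel were chosen after the results were seen. On the arrays labelled miR101 overexpression, several further groups held large single ratios without passing as lists in camera. Heat shock genes were higher for 8 of 13 and lower for 1, with the chaperones HSPH1 (2.48), HSP90AA1 (1.77) and HSPD1 (1.66) among the higher (camera adjusted p = 0.062 in limma). Inflammatory NF-kB genes were higher for 10 of 19 and lower for 3, with BIRC3 (2.53), the chemokine gene CCL2 (2.47) and the cytokine gene IL6 (1.90) ahead (adjusted p = 0.24 in limma). Genes of the unfolded protein and ATF4 response were higher for 19 of 29 and lower for 6, with DNAJB9 (2.19) and ASNS, the asparagine synthetase (1.76), ahead (adjusted p = 0.13 in limma). Of 15 small RNA pathway genes, 9 were higher and 5 lower, with DICER1, which cuts microRNA precursors, at 1.83 and AGO2, which carries them, at -0.91 (adjusted p = 0.31 in limma). With EZH2 RNAi AGO2 was 1.24, and 7 of the 15 were higher and 5 lower (adjusted p = 0.5 in limma). The adhesion gene TJP1 (2.37) led 10 higher and 5 lower of 21 epithelial genes, and CDH11 (2.72) led 7 higher and 8 lower of 20 mesenchymal genes (adjusted p = 0.4 and 0.81 in limma). HMGCS1, of sterol synthesis (2.32), led 8 higher and 11 lower of 24 cholesterol genes (adjusted p = 0.81 in limma). RB1, the retinoblastoma gene (1.91), led 4 higher and 2 lower of 9 CDK inhibitors and pocket proteins (adjusted p = 0.65 in limma), and CDKN1C (-1.26) was the lowest of them.

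With EZH2 RNAi, genes of fatty acid synthesis were lower for 8 of 13 and higher for 3, with the desaturases FADS2 (-1.60) and FADS1 (-1.08) and their regulator SREBF1 (-1.46) lowest (camera adjusted p = 0.085 in limma). Of 26 described miR-101 targets, 17 were higher and 5 lower, with PRKAA1 at 1.26 and STMN1, which destabilises microtubules, at -1.54 (adjusted p = 0.062 in limma). Epithelial genes were higher for 15 of 21 and lower for 5 (adjusted p = 0.062 in limma). Of 20 p53 target genes, 13 were higher and 6 lower (adjusted p = 0.12 in limma). GADD45A (1.40) and CDKN1A (0.68) were among the higher, and DDB2 (-0.87) and BAX (-0.86) among the lower. Of 17 DNA and histone methylation enzymes, 8 were lower and 5 higher, with the methyltransferase gene SUV39H2 at -1.51 (adjusted p = 0.43 in limma). Cholesterol genes were lower for 14 of 24 and higher for 6 (adjusted p = 0.21 in limma), and mesenchymal genes were higher for 9 of 20 and lower for 7, with SNAI2 at 1.44 and S100A4 at -1.48 (adjusted p = 0.89 in limma). ANGPTL4 (1.90) led 9 higher and 13 lower of 28 glycolysis and hypoxia genes (adjusted p = 0.93 in limma). Ribosomal proteins were higher for 21 of 47 and lower for 10 (adjusted p = 0.25 in limma), BCL2 family genes higher for 7 of 16 and lower for 6 (adjusted p = 0.71 in limma), and heat shock genes higher for 3 of 13 and lower for 4 (adjusted p = 0.99 in limma). PRC1 genes were higher for 5 of 17 and lower for 6 (adjusted p = 0.9 in limma), and CDK inhibitors lower for 5 of 9 and higher for 2 (adjusted p = 0.5 in limma).

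The other lists on the arrays labelled miR101 gave these values in limma's camera, over their tested members only. PRC1 genes were higher for 7 of 17 and lower for 9, with RYBP (1.66) and PCGF5 (1.67) highest (adjusted p = 0.74), and the methylation enzymes higher for 6 of 17 and lower for 10, with KMT2A at 1.78 and DOT1L at -1.34 (adjusted p = 0.37). HOX genes were higher for 4 of 11 and lower for 4 (adjusted p = 0.65), and developmental transcription factors higher for 6 of 23 and lower for 9 (adjusted p = 0.4). Genes described as repressed by EZH2 in cancer were higher for 5 of 21 and lower for 9 (adjusted p = 0.4). Of 20 p53 targets, 10 were higher and 5 lower (adjusted p = 0.4), of 13 fatty acid genes, 4 were higher and 6 lower (adjusted p = 0.42), of 28 glycolysis and hypoxia genes, 10 were higher and 15 lower, with CA9 at -1.64 (adjusted p = 0.37), and of 25 immediate early genes, 5 were higher and 12 lower, with DUSP6 at 1.83 (adjusted p = 0.24).

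Markers of other cell types were sparsely tested. Of 12 fibroblast markers, 6 were tested, with 0 higher and 3 lower on the arrays labelled miR101 (camera adjusted p = 0.4 in limma) and 2 higher and 2 lower with EZH2 RNAi (adjusted p = 0.98 in limma). Of 14 leukocyte markers, 8 were tested, with 0 higher and 4 lower (adjusted p = 0.24 in limma) and 5 higher and 1 lower (adjusted p = 0.5 in limma). Of 32 luminal breast and ERBB2 genes, 18 were above background in all 8 channels and 7 in none, and of 14 basal and other breast cell line markers on the arrays, 11 were above background in all 8 channels and 3 in none. ERBB2, KRT8, KRT18, KRT19 and FOXA1 were among the 18 luminal genes detected in all channels. The 7 detected in none were PGR, PIP, SCGB2A2, TFAP2A, TFAP2B, CEACAM6 and ANKRD30A. EGFR belongs to both lists and is counted in both the 18 and the 11. A signal above background does not give a level of expression. With 7 luminal genes undetected and 11 basal markers detected, whether the label SKBr3 holds was left open, since no reference profile of the line was used. Luminal genes were higher for 9 of 24 and lower for 11 on the arrays labelled miR101, with AGR2 at 2.62 (adjusted p = 0.74 in limma), and higher for 5 and lower for 9 with EZH2 RNAi, with KRT19 at -1.03 (adjusted p = 0.76 in limma). Basal markers were higher for 6 of 11 and lower for 4 on the arrays labelled miR101 (adjusted p = 0.65 in limma), and higher for 5 and lower for 5 with EZH2 RNAi, with LAMB3 at 1.49 and CD44 at 1.32 (adjusted p = 0.68 in limma).

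With the EZH2 control siRNA channel as control of the miR101 arrays, 436 genes were called at 2-fold or more, 307 higher and 129 lower. The described miR-101 targets then had a mean of -0.31 (camera adjusted p = 0.0013 in limma), NF-kB genes a mean of 0.79 (adjusted p = 5.5e-05 in limma) and G1/S genes a mean of -0.25 (adjusted p = 1.3e-04 in limma), all at the preset correlation, and each had an adjusted p = 0.51 with an estimated correlation. The ratios of 10 spike-in control transcripts were lower on the arrays labelled miR101 than with EZH2 RNAi by a median of -0.90, between -1.17 and -0.54, and by -1.02 for the arrays of scan 1 and -0.78 for those of scan 2. Whether each channel received the same amounts of spike-ins in both groups was not known. This value therefore does not separate a difference in RNA from a difference in spike-ins. On 4856 genes with 2 probes, the upstream minus the downstream probe had a median of -0.172 and -0.166 on the arrays labelled miR101 and 0.189 and 0.102 with EZH2 RNAi, and the 2 probes correlated at 0.70 and 0.669, and at 0.473 and 0.478.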
